A study of Mus musculus with 4 samples.

How the data were processed

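The data are poly(A) RNA-seq libraries of macrophages sorted from mouse lungs, 2 from chimeras with Cre-negative floxed Tmem173 marrow (WTKL) and 2 from chimeras with Lyz2-Cre floxed Tmem173 marrow (LYZKL). Per the labels' protocols, RNA was taken up in TRIzol, poly(A) RNA was selected with oligo(dT) beads, the second strand was made without marking the strand, the libraries were made with a transposase kit, and they were sequenced as 150-bp paired reads on an Illumina HiSeq instrument. Because strand was not marked, reads of a gene and of an overlapping gene on the other strand cannot be told apart. The labels also describe a droplet single-cell protocol; no single-cell matrix was used here. All 4 libraries carry the same batch label, so no batch could be compared. Samples were assigned to groups and replicate numbers by their titles.

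The authors deposited 1 table of FPKM values, reads scaled by transcript length and library total, with 27433 rows and 1 column per library. The submitters' processing notes name HISAT2 2.0.5, featureCounts 2.0.0, Cell Ranger 6.1.2 and the mouse build mm10, with no roles or order. The annotation, the gene length and the total by which reads were divided are not given in the sources used here. FPKM divides by gene length and library total, so a change in a few abundant genes shifts the share left to all others. The column sums were 368792 and 373686 in the WTKL libraries and 363775 and 363972 in the LYZKL libraries, and the 10 most abundant genes held 12.5% to 16.2% of them. The gene names in the table are in upper case and are printed here in mouse style. Of the rows, 110 share 55 names and were kept out of the lists, and 22 have a number in place of a name. Names of 26196 rows (95.49%) matched 1 gene each in GENCODE release M21, whose coordinates on GRCm38, the assembly of mm10, are given.

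Although the table holds no counts, its low values are multiples of the worth of 1 read. With the annotated exon length of each gene, values under 0.3 FPKM gave library totals of 15466117 and 22867836 (WTKL replicates 1 and 2) and 16453512 and 18322164 (LYZKL replicates 1 and 2). Of the tested rows, 10010 then gave whole reads at the annotated length (tolerance 0.05 read) and 2666 at a length searched between 50 and 100000 (tolerance 0.003), 99.88% in all. The 15 others comprise 13 with a 0 in some library, which were not searched over lengths, and Tmem173 and Cd38. Of 1000 sets of random values, the search accepted 1. Counting error is small for most genes named, and the intervals given for reads cover counting error only. Replicates differed by more than counting error, with a chi-square per degree of freedom of 5.65 between the WTKL libraries and 5.37 between the LYZKL libraries, so no library looked like another deposited again and all were kept. This does not show that they came from separate animals. Pearson correlations of log2 values across genes were 0.9796 within WTKL, 0.9798 within LYZKL and 0.9684 to 0.98 between groups.

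The comparison of LYZKL with WTKL was made with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend, over the 12691 genes with a mean of at least 1 FPKM over the 4 libraries. Fold changes are on that scale, which understates the change of low genes. Tests were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05; all adjusted p-values are from limma and its camera, fry and voom functions. The moderated tests had 4.34 degrees of freedom, 2 from the samples and 2.34 from the prior. In total 33 lists were fixed, 21 of pathways and 12 of cell type markers. The 31 with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. Eosinophil and mast cell markers had 0 tested members and red blood cell markers 1, so they were not tested. Members were also tested with the adjustment over the list alone. Camera at the preset correlation called 15 lists, 3 higher and 12 lower. With an estimated correlation it called 0, the smallest adjusted p being 0.41, and fry, which asks whether a list moves on balance 1 way, called 0, the smallest adjusted p being 0.1.

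Genes were named by a rule: Tmem173 and Lyz2, the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap and whose mean was at least 2 FPKM, without gene models named Gm or LOC, Rik clones, microRNA, small nucleolar RNA and pseudogene names, and up to 4 members of smallest p per list, with the 2 most abundant of a cell type list. Values are printed for such examples from the lists past the threshold in camera and a few of the others. Some examples that the rule selects are not reported here. Other list members are named where a list had few that passed, after their values were seen. Groups, lists, test, naming rule and most alternatives were fixed before the data were examined. The alternatives were other pseudocounts (0.1 and 5), no filter or a mean of at least 5 FPKM, quantile normalization, median scaling, no trend, the replicate number as a block, each library left out, an adjusted p of 0.1, a 2-fold minimum, an estimated correlation and fry. A limma-voom test on rebuilt reads, and the test without Tmem173 and Cd38, were added later.

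The procedure was tested on simulated data with 200 genes changed between groups of 2 libraries at these depths. In the simulated LYZKL against WTKL comparison, limma on log2(FPKM + 1), run on 12381 genes, recovered 6.0% of changes of 1.5-fold, 30.2% of 2-fold and 66.7% of 4-fold, with 4 false calls among 69. The voom test, run on 12676 genes, recovered 58.2%, 79.1% and 86.4% of the same sizes, with 9 false calls among 158. The simulation gave genes of like read level the same spread and drew each gene independently. Its shares of recovered and false calls therefore need not hold for the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.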

Results

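Poly(A) RNA was profiled in macrophages sorted from the lungs of tumor-bearing chimeric mice. The recipients (KL mice) were of a genotype in which inhaled adenoviral Cre starts lung tumors. They were irradiated and given bone marrow whose Tmem173 gene was floxed, either without Cre (WTKL) or with Cre expressed from the Lyz2 locus (LYZKL). Tmem173 encodes STING, the adaptor that passes the cytosolic DNA signal of cGAS on to interferon and NF-kB signalling, and Lyz2-Cre is active mainly in macrophages and neutrophils. Cells that were CD11b positive, Ly6G negative, CD64 positive and low for Siglec-F were collected 8 weeks after the virus. There were 2 libraries in each group, and their values were deposited as FPKM. The library totals implied by the size of 1 read in that table were 15466117 and 22867836 reads for WTKL replicates 1 and 2, and 16453512 and 18322164 for LYZKL replicates 1 and 2. At those totals 1 read in a gene of 1 kb is worth 0.0437 to 0.0647 FPKM. Both LYZKL totals lay between the WTKL totals. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

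The design asks what loss of Tmem173 in Lyz2-expressing, marrow-derived cells does to the transcripts of these lung macrophages. The WTKL marrow carried no Cre, so Tmem173 loss and the Cre allele in Lyz2 go together in LYZKL. For every gene below, their effects cannot be told apart. The floxed gene itself was lower in both LYZKL libraries. Tmem173 lies on the minus strand of chromosome 18 from 35733679 to 35740554 (mm10). Its level was 15.3 ± 0.0825 FPKM (SD, n = 2) in WTKL and 4.89 ± 0.194 FPKM (SD, n = 2) in LYZKL, 31.9% of the WTKL level. On the scale of log2(FPKM + 1) it fell by 1.47 (SE 0.06, adjusted p = 0.0452, limma). The labels do not say which exons are floxed, and a value per gene can include reads from exons that Cre leaves in place. No transcript length gives whole read numbers for Tmem173 in all 4 libraries together, which held for 2 of the 19226 rows above 0 in all 4 libraries, Tmem173 and Cd38. With any 1 library left out, the adjusted p of Tmem173 lay above the threshold of 0.05, at 0.223 without WTKL replicate 1, 0.215 without WTKL replicate 2, 0.195 without LYZKL replicate 1 and 0.0997 without LYZKL replicate 2.

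Lyz2, which encodes the lysozyme of macrophages and whose locus holds Cre in LYZKL marrow, lies on the minus strand of chromosome 10 from 117277331 to 117282321. It was measured at 9896 ± 475 FPKM (SD, n = 2) in WTKL and 3132 ± 733 FPKM (SD, n = 2) in LYZKL. The log2 difference was −1.68 (SE 0.18), with an adjusted p of 0.0641 in limma, just above the threshold. Since Cre lies in this locus, a change made by the Cre allele and an effect of Tmem173 loss cannot be told apart here. Reads rebuilt from the FPKM values gave 187190 and 296228 Lyz2 reads in WTKL replicates 1 and 2, and 54455 and 84675 in LYZKL replicates 1 and 2. Tested on such reads with limma-voom, the Lyz2 difference passed, with an adjusted p of 2.96e-05. It also passed when only genes with a mean of at least 5 FPKM were tested, with an adjusted p of 0.0286, and its adjusted p over all alternatives ranged from 2.96e-05 to 0.258.

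Across the transcriptome, a small set of genes separated the groups past the adjusted threshold. Genes induced by interferon-gamma and the nitric oxide synthase Nos2 were among those that fell in LYZKL, and the cytokine gene Il23a, the prolyl hydroxylase gene Egln3 and Siglecf were among those that rose. Of 12691 genes with a mean of at least 1 FPKM, 20 rose and 17 fell, 37 in all, with adjusted p between 0.0452 and 0.0489 in limma. At an unadjusted p under 0.05 there were 1385 genes on the higher and 996 on the lower side, 2381 in total, where 635 are expected by chance. The groups did not overlap for 6625 genes, 52.2% of those tested, against 33.3% by chance. The count of 37 sits at the edge of the adjustment: limma gave 0 genes with any 1 library left out, with no filter, without the trend, or with the rows of Tmem173 and Cd38 removed, and 340 among genes with a mean of at least 5 FPKM. Without WTKL replicate 1, WTKL replicate 2, LYZKL replicate 1 or LYZKL replicate 2, there were 1609, 1701, 1413 and 2280 genes at an unadjusted p under 0.05. The corresponding numbers were 3136 with no filter, 2255 without the trend and 2379 without those rows, while limma-voom on rebuilt reads called 1181 genes, 735 higher and 446 lower. With 2 libraries against 2, an exact permutation test of any single gene cannot give a two-sided p below 0.333.

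The named genes that fell in LYZKL included an antibody gene segment, a lysozyme, Tmem173 itself, Cd38, 2 genes tied to nitric oxide synthesis (Nos2 and Ass1) and genes of the interferon response. All passed in limma with adjusted p from 0.0452 to 0.0489. Nos2 (chromosome 11, 78920787 to 78960254), the inducible nitric oxide synthase, was at 20.8 and 21.2 FPKM in the WTKL libraries and at 8.18 and 9.05 FPKM in the LYZKL libraries, and fell by 1.20 on the log2 scale (SE 0.07). Ass1, whose enzyme rebuilds arginine from the citrulline that nitric oxide synthesis leaves, fell by 0.80 (SE 0.06), from 46.5 ± 0.831 to 26.3 ± 1.35 FPKM (SD, n = 2 per group). Cxcl9 (chromosome 5, 92321347 to 92328079), a chemokine that attracts T cells, was at 199.3 ± 1.00 FPKM in WTKL and 111.9 ± 5.49 FPKM in LYZKL, and fell by 0.83 (SE 0.05). The interferon-inducible GTPase genes Gbp5 and Tgtp2 fell by 0.87 and by 0.86 (SE of the Gbp5 change 0.06), to 53.9% and 53.6% of their WTKL levels. Dtx3l, a ubiquitin ligase gene of the interferon response, fell by 0.90, Dnase1l3, a secreted nuclease gene, fell by 1.00, and Pla2g2d, a secreted phospholipase gene, fell by 0.73. Cd38, an enzyme that consumes NAD at the cell surface, lies on chromosome 5 from 43868553 to 43912375 and fell by 1.44 (SE 0.09), from 10.7 ± 0.558 to 3.31 ± 0.352 FPKM. Its values, like those of Tmem173, give whole read numbers in all 4 libraries at no transcript length. Lyz1, a lysozyme gene next to Lyz2 on chromosome 10 (117287797 to 117292868), fell by 1.51, from 23.7 ± 1.55 to 7.65 ± 0.0663 FPKM. Lyz1 and Lyz2 are close copies, so reads could have been shared between them, and the Lyz1 value is uncertain for that reason. Ighv1-59, an immunoglobulin heavy chain variable segment on chromosome 12 (115335082 to 115335514), fell by 3.20 (SE 0.12). It rested on 154 reads over the WTKL libraries and 4 over the LYZKL libraries, a ratio of 0.0286 per library total (exact binomial 95% interval 0.0077 to 0.0748, counting error only). Over the 79 immunoglobulin variable segments tested, the median SD of log2 values was 1.66 within WTKL and 1.37 within LYZKL, against 0.07 over all genes.

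On the higher side, a cytokine subunit, a surface receptor of the sorting gate and an oxygen-sensing enzyme were among the 12 named genes, with adjusted p from 0.0452 to 0.0483 in limma. Il23a (chromosome 10, 128296139 to 128298752), which encodes the subunit specific to the cytokine IL-23, rose from 74.3 ± 2.17 to 172.1 ± 14.8 FPKM (SD, n = 2 per group), a log2 change of 1.20 (SE 0.08). Siglecf (chromosome 7, 43351341 to 43359531), the gene of the sialic acid receptor by which the cells were sorted as low, rose from 6.42 ± 0.533 to 15.6 ± 0.0403 FPKM, a log2 change of 1.16 (SE 0.07). Neutrophil markers were higher in the same LYZKL libraries, with a list median of 0.89 on the log2 scale. Egln3 (chromosome 12, 54178981 to 54203860), a prolyl hydroxylase that marks hypoxia-inducible factors for degradation, rose by 1.78 (SE 0.13), from 5.03 ± 0.347 to 19.8 ± 3.43 FPKM. Log2 rises of 1.21 for Amer2, a regulator of Wnt signalling, 1.11 for the scaffold gene Cass4 and 1.05 for Cacfd1 were measured. Mid1, a ubiquitin ligase bound to microtubules, rose by 0.94, the myeloid receptor gene Tarm1 by 0.69, and Tnfsf14, the tumor necrosis factor family ligand LIGHT, by 0.67. RP23-314A15.5 and RP23-312B17.3, which are gene models named after clones, rose by 1.70 and 1.24. The mitochondrial glycine tRNA gene mt-Tg rose by 0.96 on 10 to 24 reads per library, and limma-voom on those reads gave it an adjusted p of 0.181. Another 8 genes that rose and 5 that fell are gene models the naming rule leaves out, microRNA genes, a pseudogene or a lower-ranked gene, and carry no description here.

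**Figure D1:**
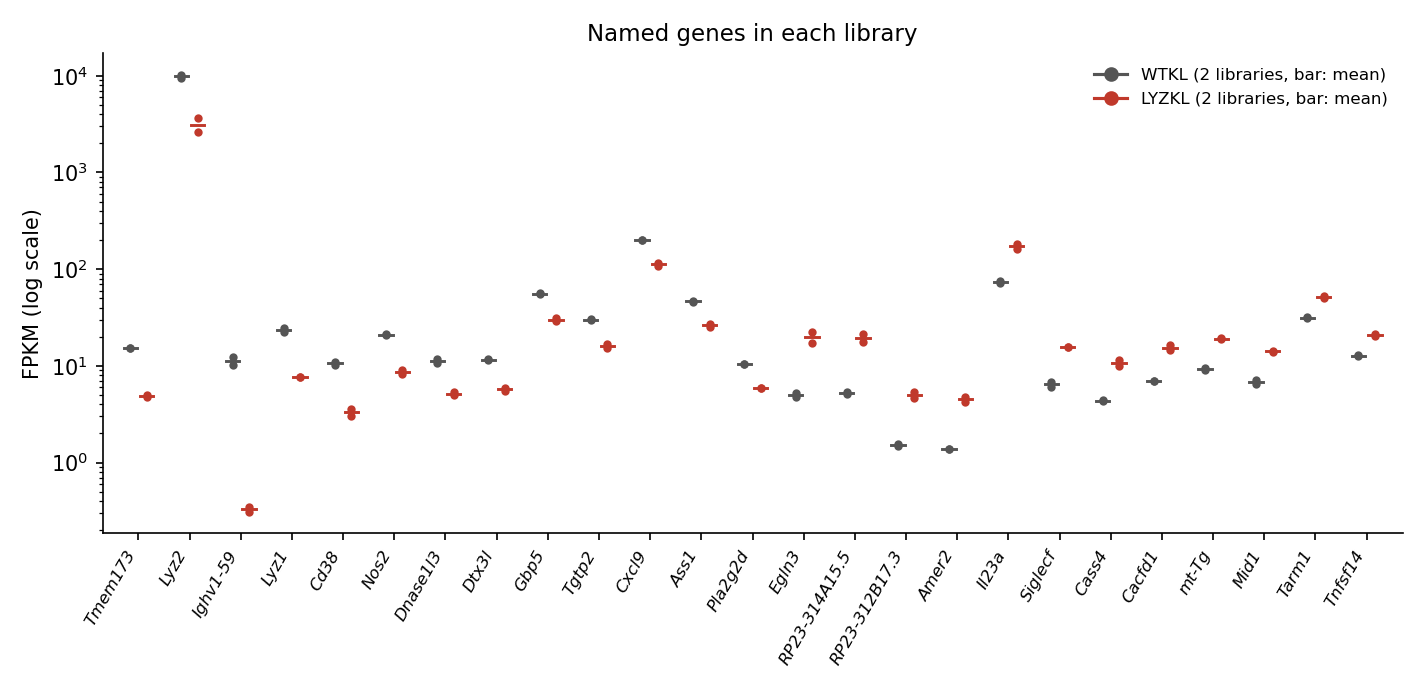
The FPKM of each named gene is plotted on a log axis, with a point for each of the 2 WTKL libraries (gray) and the 2 LYZKL libraries (red) and a bar at the group mean. The Tmem173 values of LYZKL, 5.02 and 4.75 FPKM, lie below both WTKL values, and the Siglecf values of LYZKL, 15.5 and 15.6 FPKM, lie above both WTKL values of 6.05 and 6.80 FPKM.

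Genes of the interferon response were lower in LYZKL as groups. Of 24 measured genes of the interferon-gamma response, 22 fell and 0 rose when adjusted over the list alone, while over all genes tested 3 passed in limma, Cxcl9, Gbp5 and Tgtp2, all of which fell. The list's median log2 change was −0.69. Cxcl10, another T cell chemokine, fell from 25.8 ± 1.51 to 13.3 ± 1.05 FPKM (SD, n = 2 per group) when adjusted over the list alone, at an adjusted p of 0.0579 over all genes. The camera test with its preset correlation gave the list an adjusted p of 4.4e-20, and an adjusted p of 0.41 with an estimated correlation. Of 47 measured type I interferon-stimulated genes, 34 fell and 3 rose when adjusted over the list alone and 0 passed over all genes tested (38 at an unadjusted p under 0.05), with a median log2 change of −0.47. The antiviral ubiquitin-like gene Isg15 was at 44.9 ± 2.00 FPKM in WTKL and 30.3 ± 0.117 in LYZKL, and Oasl1 at 11.4 ± 0.392 and 7.42 ± 0.184. The 3 that rose were Slfn1, from 27.7 ± 0.311 to 41.1 ± 1.51 FPKM, Slfn4 and Trim30a. Camera gave this list an adjusted p of 6.1e-18, and an adjusted p of 0.41 with an estimated correlation. On rebuilt reads, limma-voom called 22 interferon-gamma genes and 31 type I genes lower over all genes tested, and 0 and 2 higher. Markers of T and NK cells, which can secrete interferon-gamma, had a median of −0.46 in the same libraries, and neutrophil markers one of 0.89.

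Antigen presentation genes moved the same way. Of 22 MHC class I genes, 17 fell and 0 rose when adjusted over the list alone (0 over all genes tested in limma and 19 at an unadjusted p under 0.05), with a median log2 change of −0.37. The nonclassical gene H2-T23 was at 131.5 ± 0.825 FPKM (SD, n = 2) in WTKL and 97.7 ± 4.78 in LYZKL, H2-T22 at 37.7 ± 1.08 and 28.4 ± 1.31, H2-Q6 at 246.7 ± 1.65 and 174.1 ± 15.8, and H2-Q4 at 103.9 ± 0.487 and 79.6 ± 4.53. These genes have near-identical copies, between which reads could have been split. The class I list had an adjusted p of 3.6e-13 in camera, and an adjusted p of 0.41 with an estimated correlation. Of 16 MHC class II genes, 11 fell and 1 rose, the costimulatory gene Cd80, when adjusted over the list alone, against 0 over all genes tested and 13 at an unadjusted p under 0.05. H2-Eb1 was at 2186 ± 42.0 FPKM in WTKL and 1527 ± 142 in LYZKL, H2-Aa at 372.0 ± 1.24 and 273.7 ± 9.49, H2-DMa at 35.5 ± 1.14 and 27.5 ± 0.205, and H2-Oa at 4.33 ± 0.143 and 2.47 ± 0.153. The class II median was −0.35, with an adjusted p of 2.2e-07 in camera and an adjusted p of 0.41 with an estimated correlation. Dendritic cell markers, a class of cells rich in MHC class II, had a median of −0.25, with both members that fell, Irf8 and Bst2, also in the interferon lists, and T and NK cell markers one of −0.46 in the same comparison. With limma-voom on rebuilt reads 15 class I and 12 class II genes were lower and 0 and 1 were higher over all genes tested.

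Inflammatory genes split in direction. Of 35 cytokine, chemokine and feedback genes of the NF-kB pathway, 18 rose and 10 fell when adjusted over the list alone, and over all genes tested Il23a rose and Nos2 fell in limma. The neutrophil-attracting chemokine gene Cxcl2 went from 852.0 ± 32.6 to 1864 ± 225 FPKM (SD, n = 2 per group) and the macrophage growth factor gene Csf1 from 11.5 ± 1.06 to 28.8 ± 3.24 FPKM, each with an adjusted p of 0.0579 over all genes. Cxcl3, Il1a, Il1b, Nlrp3, Ccl3 and Tnf were among the others that rose over the list alone, and Ccl2, Ccl5, Ccl7, Ccl8, Ccl12, Cxcl16, Cd40, Nfkb1 and Il12b, several of which interferon also induces, were the others that fell. The list median was 0.21, with an adjusted p of 0.015 in camera and an adjusted p of 0.8 with an estimated correlation. Without WTKL replicate 2 the adjusted p of camera was 0.24, and with a mean of at least 5 FPKM it was 0.055. Immediate-early genes, a class that also responds to tissue dissociation, were higher: 19 of 26 rose and 0 fell when adjusted over the list alone, with 0 over all genes tested, 20 at an unadjusted p under 0.05 and 19 by limma-voom, and a median of 0.38. Egr1 was at 46.2 ± 0.883 FPKM in WTKL and 104.1 ± 19.5 in LYZKL, Egr3 at 4.99 ± 0.278 and 11.6 ± 1.71, Ier2 at 34.7 ± 2.73 and 51.6 ± 3.60, and Nr4a1 at 135.4 ± 6.67 and 197.3 ± 17.2. That list had an adjusted p of 2.3e-10 in camera and an adjusted p of 0.41 with an estimated correlation. In the same LYZKL libraries the neutrophil markers, whose cells express many of these inflammatory genes, had a median of 0.89.

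Markers of other cell types also differed between the groups. Of 15 neutrophil markers, 9 rose and 0 fell when adjusted over the list alone and 0 passed over all genes tested in limma (9 at an unadjusted p under 0.05, and 9 by limma-voom), with a median log2 change of 0.89. The calgranulin gene S100a9 was at 1812 ± 353 FPKM (SD, n = 2) in WTKL and 3970 ± 1259 in LYZKL, and S100a8 at 123.8 ± 15.8 and 232.3 ± 45.4. The chemokine receptor gene Cxcr2 was at 20.3 ± 0.906 and 55.8 ± 10.7 FPKM, Mmp9 at 12.0 ± 0.932 and 36.3 ± 7.76, Hdc at 47.9 ± 4.14 and 100.1 ± 14.2, and Csf3r at 62.2 ± 6.36 and 137.2 ± 24.5. Ly6g, the gene of the marker by which neutrophils were gated out, had 14 and 9 reads in the WTKL libraries and 15 and 17 in the LYZKL libraries. Camera gave the neutrophil list an adjusted p of 2.8e-07, and an adjusted p of 0.41 with an estimated correlation. Of 22 T and NK cell markers, 13 fell and 0 rose when adjusted over the list alone (0 over all genes tested in limma, 17 at an unadjusted p under 0.05, and 11 by limma-voom), with a median of −0.46. The T cell receptor gene Trac was at 10.7 ± 0.581 FPKM in WTKL and 6.32 ± 0.262 in LYZKL, the granzyme gene Gzmb at 8.68 ± 0.940 and 3.36 ± 0.633, and Cd8b1 at 7.87 ± 0.0338 and 4.29 ± 0.853. The most abundant of these markers, Thy1 and Il7r, were at 25.5 ± 0.582 and 21.7 ± 1.93 FPKM in WTKL and at 15.9 ± 5.54 and 17.7 ± 0.759 in LYZKL. The T and NK list had an adjusted p of 1.9e-12 in camera and an adjusted p of 0.41 with an estimated correlation.

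Among 15 dendritic cell markers 2 fell, Irf8 and Bst2, and 1 rose, Cd24a, when adjusted over the list alone (0 over all genes tested in limma, 7 at an unadjusted p under 0.05, and 4 by limma-voom), with a median of −0.25. Irf8 is also in the interferon-gamma list and Bst2 in the type I list. Irf8 was at 44.9 ± 0.448 FPKM (SD, n = 2) in WTKL and 30.3 ± 2.48 in LYZKL, Cd24a at 27.6 ± 0.957 and 46.6 ± 6.25, Bst2 at 46.5 ± 0.949 and 39.0 ± 1.27, Itgae at 9.21 ± 0.268 and 5.60 ± 1.71, and Naaa at 152.4 ± 8.37 and 149.8 ± 4.08. The list's adjusted p was 0.014 in camera, with an adjusted p of 0.57 with an estimated correlation and 0.13 without LYZKL replicate 1. Of 13 B and plasma cell markers 0 passed in limma, adjusted over the list alone or over all genes, with 3 at an unadjusted p under 0.05 and 1 by limma-voom. Their median was −0.32, with an adjusted p of 0.0068 in camera, an adjusted p of 0.57 with an estimated correlation, 0.38 without WTKL replicate 2 and 0.5 with a mean of at least 5 FPKM. Pax5 was at 1.77 ± 0.0301 FPKM in WTKL and 0.932 ± 0.338 in LYZKL, Ighm at 23.1 ± 8.68 and 17.2 ± 5.47, and Igkc at 181.5 ± 95.9 and 143.1 ± 70.2.

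Smaller shifts over whole lists were measured for housekeeping and resident macrophage genes, in libraries whose neutrophil markers had a median of 0.89 and whose T and NK cell markers had one of −0.46. All members of the ribosomal protein list that reached an unadjusted p under 0.05, 19 of 46, were lower in LYZKL, with a median log2 change of −0.16, but 0 passed in limma adjusted over the list alone or over all genes, and 4 passed by limma-voom. The list's adjusted p was 2.2e-12 in camera and an adjusted p of 0.41 was found with an estimated correlation. Rpl35 was at 499.9 ± 8.49 FPKM (SD, n = 2) in WTKL and 424.1 ± 17.9 in LYZKL, Rpl10 at 137.9 ± 3.83 and 120.4 ± 2.36, Rpl11 at 80.2 ± 0.178 and 69.6 ± 1.75, and Rps27 at 83.1 ± 6.60 and 66.2 ± 1.48. Ribosomal protein genes have many processed pseudogenes, which could have taken part of their reads. Of 24 complement and resident macrophage genes, the platelet factor gene Pf4 and the Fc receptor gene Fcgr1 fell and Fcrls rose when adjusted over the list alone, with 0 over all genes tested, 10 at an unadjusted p under 0.05 and 5 by limma-voom. Pf4 was at 28.9 ± 0.868 FPKM in WTKL and 20.2 ± 0.159 in LYZKL. This list's median was −0.15, with an adjusted p of 9.6e-05 in camera and an adjusted p of 0.41 with an estimated correlation. Of 22 phagocytosis and scavenger receptor genes, Fcgr4, Cd5l, Fcgr1 and Msr1 fell and Marco and Clec4n rose when adjusted over the list alone, against 0 over all genes tested, 8 at an unadjusted p under 0.05 and 7 by limma-voom. Cd5l, a secreted protein of resident macrophages, was at 53.0 ± 6.46 FPKM in WTKL and 31.3 ± 4.37 in LYZKL, and the scavenger receptor gene Marco at 23.8 ± 2.01 and 37.0 ± 5.03. The median was −0.10, with an adjusted p of 0.015 in camera, an adjusted p of 0.41 with an estimated correlation and 0.11 without WTKL replicate 2.

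Cholesterol synthesis genes and mitochondrially encoded genes passed camera only narrowly, in the same libraries with neutrophil markers at a median of 0.89 and T and NK cell markers at −0.46. Of 21 cholesterol genes 0 passed in limma over the list alone or over all genes, 2 had an unadjusted p under 0.05 and 0 passed by limma-voom. The sterol enzyme gene Fdps was at 7.11 ± 0.601 FPKM (SD, n = 2) in WTKL and 5.85 ± 0.290 in LYZKL. Their median was −0.07 and their adjusted p 0.034 in camera, with an adjusted p of 0.41 with an estimated correlation, 0.12 without WTKL replicate 2 and 0.17 without LYZKL replicate 1. Of 13 mitochondrially encoded genes 0 passed in limma over the list alone or over all genes, with 1 at an unadjusted p under 0.05 and 1 by limma-voom. The oxidase subunit gene mt-Co1 was at 2674 ± 164 FPKM in WTKL and 2181 ± 81.4 in LYZKL, and mt-Nd5 at 1533 ± 81.9 and 1377 ± 52.9. This list had a median of −0.09 and an adjusted p of 0.025 in camera, and an adjusted p of 0.77 with an estimated correlation. That adjusted p was 0.48 without WTKL replicate 2, 0.31 without LYZKL replicate 2, 0.12 after quantile normalization and 0.052 with no filter.

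**Figure D2:**
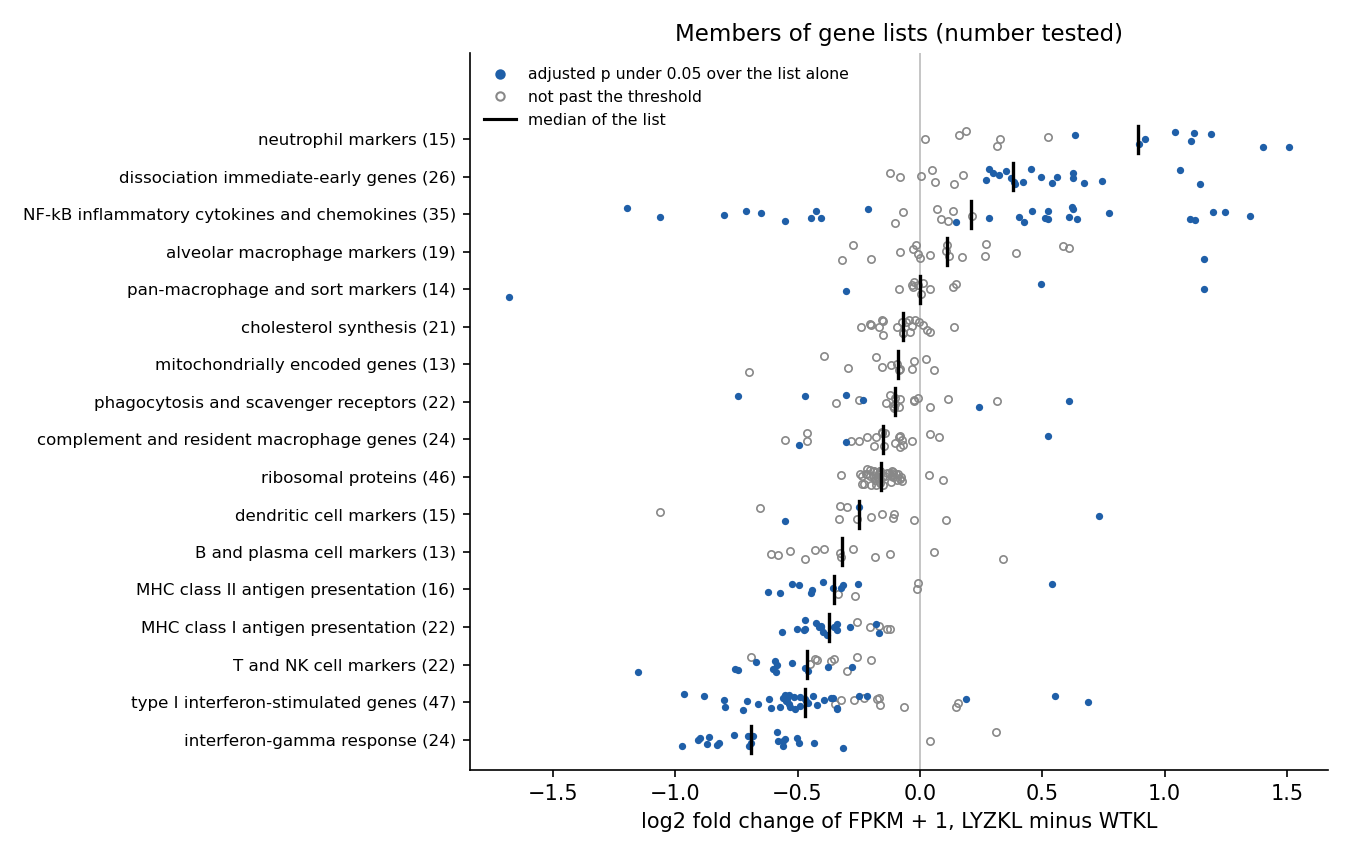
Every point is the log2 fold change of 1 list member (horizontal axis, log2 of FPKM + 1, LYZKL minus WTKL), filled where its adjusted p over the list alone is under 0.05, with a black bar at the list median. Shown are the 15 lists past the threshold in camera and the alveolar and pan-macrophage markers, with medians from −0.69 for the interferon-gamma response to 0.89 for neutrophil markers.

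The remaining 16 lists did not pass in camera. The pan-macrophage and sort markers had a median of 0.00 over 14 genes (adjusted p = 0.82), and Cd68, Csf1r and Adgre1 had log2 differences of 0.00, −0.03 and 0.04. In that list Siglecf and Cd33 rose and Lyz2 and Fcgr1 fell when adjusted over the list alone. Alveolar macrophage markers had a median of 0.11 over 19 genes (adjusted p = 0.21), of which Siglecf alone rose over the list. Without WTKL replicate 2, whose mean log2 value over the alveolar markers was 5.31 against 5.03 in WTKL replicate 1, that list's adjusted p was 5.6e-05, on the higher side. Monocyte markers had a median of −0.12 (adjusted p = 0.64), with 3 higher and 2 lower adjusted over the list alone, among them Nr4a1 and Lyz1. Epithelial and tumor cell markers had a median of −0.13 (adjusted p = 0.52, and 0.011 without WTKL replicate 1), fibroblast and smooth muscle markers one of −0.12 (adjusted p = 0.52) and endothelial markers one of 0.11 (adjusted p = 0.92).

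Genes of the sensing pathway around STING did not move as a group. Their median was −0.03 over 22 genes (adjusted p = 0.34), and 2 fell over the list alone, the interferon-inducible gene Ifi203, with a log2 change of −0.50, and the nucleotide hydrolase gene Samhd1, with −0.39. Alternatively activated macrophage genes had a median of −0.12 (adjusted p = 0.062, 0.013 without WTKL replicate 2 and 0.045 with limma-voom on rebuilt reads), and 1 of 23, the chemokine gene Ccl24, fell over the list alone, with a log2 change of −0.87. Lipid-associated tumor macrophage genes had a median of 0.02 (adjusted p = 0.39), and their member of smallest p, Spp1, had a log2 difference of 0.37. Glycolysis and hypoxia genes had a median of 0.00 (adjusted p = 0.82), with Egln3 higher and Hk3 lower over the list alone. The unfolded protein response had a median of 0.06 (adjusted p = 0.089), with 3 genes that rose over the list alone, Ppp1r15a, Atf3 and Chac1, and an adjusted p of 0.049 with no filter. Immune checkpoint and T cell suppression genes had a median of −0.07 (adjusted p = 0.52), with 4 that rose over the list alone, Vsir, Siglece, Arg2 and Cd80, and 4 that fell, Nos2, Cd274, Cd86 and Vsig4. Matrix remodeling and angiogenesis genes had a median of −0.11 (adjusted p = 0.29), with Mmp9 and Hbegf higher and Mmp2 lower over the list alone. Oxidative phosphorylation had a median of −0.02 (adjusted p = 0.52), lysosome and autophagy 0.05 (adjusted p = 0.52) and the cell cycle 0.02 (adjusted p = 0.82), each with 0 members past limma over the list alone. In those 3 lists 2, 6 and 1 members had an unadjusted p under 0.05, and limma-voom called 0, 3 and 1.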

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

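The voom test on rebuilt reads and the test without the rows of Tmem173 and Cd38 were chosen after the data had been seen; the other alternatives were planned. The count of 37 changed genes (20 higher, 17 lower) stayed within 1.5 times with pseudocounts of 0.1 (37) and 5 (27), quantile normalization (39) and median scaling (26, of which 12 higher). In limma it was 0 (0 higher, 0 lower) with no filter, without the trend, with the replicate number as a block, without Tmem173 and Cd38, and 0 to 0 with each library left out. At an unadjusted p under 0.05 these settings gave 3136, 2255, 2399, 2379 and, by library left out, 1413 to 2280 genes, while limma-voom called 1181. Leaving out a library or adding a block leaves 1 residual degree of freedom; with a library left out, the lone sample is assumed to vary like the other group. Removing Tmem173 and Cd38 takes away 2 of the smallest p-values, on which the adjusted p of the other calls leaned. A mean of at least 5 FPKM, with 6834 genes tested, gave 340 (204 higher, 136 lower), voom 1181 (735 higher, 446 lower), an adjusted p of 0.1 502 (309 higher, 193 lower), and a 2-fold minimum 22 (16 higher, 6 lower). Apart from the smaller sets tested or kept, the cause was not tested. All 37 genes kept their direction in every setting that tested them, and voom called 30 of the 35 it tested. They were chosen for small p-values in these same libraries, which every setting reuses, so this is no independent support.

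Under the replicate block the Tmem173 change was −1.47, past the threshold no longer (adjusted p = 0.0701). The numbers were not taken to pair the libraries: no label says what they share, and the deviations of the libraries numbered 1 from their group means correlated at 0.16 across genes. The block moved no list across the threshold. Tmem173 was at −1.47 also with no filter (adjusted p = 0.148) and without the trend (adjusted p = 0.0763), and at −1.50 to −1.44 with a library left out, all above the threshold; the adjusted p ranged from 0.0168 to 0.223 over its alternatives. Lyz2, above the threshold in the main test, passed with a mean of at least 5 FPKM (−1.68, adjusted p = 0.0286) and with voom (−1.68, adjusted p = 2.96e-05). Its adjusted p ranged up to 0.258, and for both genes the cause was not tested.

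Of the lists past the threshold in camera, 3 higher and 12 lower, 0 higher and 0 lower passed with an estimated correlation, and 0 and 0 with fry. The estimate was 0.581 for the interferon-gamma list, 0.506 for T and NK cell markers and 0.487 for MHC class I. It was 0.337 for type I interferon genes and 0.331 for neutrophil markers. All these lie far above the preset 0.01, so the small adjusted p-values of those lists in camera rest on that setting. Correlation between members does not account for the loss in every list. The estimate was −0.004 for phagocytosis and scavenger receptor genes and 0.019 for complement and resident macrophage genes, near the preset. Both lists still went to an adjusted p of 0.41 in camera. With an estimate, camera uses the 2 residual degrees of freedom of the libraries, so the 0.41 shared by many lists says little about any 1 list. The interferon-gamma, type I interferon, MHC class I and II, T and NK cell, neutrophil, immediate-early, ribosomal and complement lists passed in the other 14 alternatives. Directions turned in 10 lists, all above the threshold in the main test and where they turned. The adjusted p where each turned stands first and its range with a library left out second. Without WTKL replicate 1 these were lipid-associated genes (0.97, 0.12 to 0.97), cell cycle (0.82, 0.51 to 0.89), checkpoint genes (0.98, 0.12 to 0.99), alveolar macrophage markers (0.35, 5.6e-05 to 0.44) and monocyte markers (0.92, 0.18 to 0.92). Without WTKL replicate 2 they were oxidative phosphorylation (0.91, 0.21 to 0.91), epithelial markers (0.46, 0.011 to 0.64) and endothelial markers (0.91, 0.49 to 0.99). Leaving out LYZKL replicate 1 turned pan-macrophage markers (0.83, 0.7 to 0.91), and leaving out LYZKL replicate 2 cell cycle (0.89) and checkpoint genes (0.99). Quantile normalization turned endothelial (0.98) and pan-macrophage markers (0.75), no filter endothelial markers (0.66), and a mean of at least 5 FPKM glycolysis (0.83). Over all alternatives the adjusted p of these 10 lists ranged from 5.6e-05 to 0.99. Naaa was at 0.03 without WTKL replicate 2 and at 0.00 without LYZKL replicate 1 (log2, −0.08 to 0.03 with a library left out), and Igkc at 0.24 and 0.19 (−0.89 to 0.24). Counting error is widest for genes of few reads, such as Ighv1-59 with a ratio interval of 0.0077 to 0.0748. The gene mt-Tg, past the threshold in limma, had an adjusted p of 0.181 in voom (the cause was not tested), and no other named gene that voom tested lost its call.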

Other observations

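The tests on the interferon-gamma list by cell markers, those on Siglecf, and those on Tmem173 and Cd38 other than the search over lengths were chosen after the result was seen; the tests of depth and of length were written before. Antibody gene segments as a class varied widely between libraries of 1 group. Of 79 immunoglobulin variable segments tested, 31 were on the higher and 48 on the lower side in LYZKL, and 1, Ighv1-59, passed in limma. The median SD of log2 values was 1.66 within WTKL and 1.37 within LYZKL for these segments, against 0.07 for all genes in both groups. The most abundant segment was Ighv1-80 in WTKL replicate 1, with 55.1 FPKM or 26.3% of the sum over variable segments, Ighv2-2 in LYZKL replicate 1, with 46.5 FPKM or 14.8%, and Igkv10-96 in WTKL replicate 2 and LYZKL replicate 2, with 59.0 and 83.0 FPKM or 8.4% and 14.2%. Ighv1-80 itself was at 0.346 FPKM in LYZKL replicate 1 and 43.5 FPKM in LYZKL replicate 2. Igkv6-23 was at 0.350 and 5.57 FPKM in WTKL and at 39.4 and 26.9 FPKM in LYZKL, and Ighv8-8 at 33.6 and 28.8 FPKM in WTKL and at 0.340 and 3.20 FPKM in LYZKL, both above the threshold in limma (adjusted p = 0.138 and 0.0816).

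Of the interferon genes, Ifnb1 and Ifng were looked up. Ifnb1, the beta interferon that STING induces, had 1 read in WTKL replicate 1 and 0 in the other libraries. Ifng had 58 and 81 reads in WTKL and 37 and 54 in LYZKL, which is 3.11 and 2.94 against 1.86 and 2.44 FPKM. Of 9 T cell receptor variable segments tested, 8 were on the lower side in LYZKL, with a median log2 difference of −0.76, and 0 passed in limma.

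The fall of the interferon-gamma response genes in LYZKL was set against technical explanations. Dilution of macrophage RNA by other cells would lower macrophage markers as far as the list, whose median was −0.69. However, 12 pan-macrophage markers had a median of −0.001 (quartiles −0.03 and 0.06). Lyz2, at −1.68 and the site of Cre, and Siglecf, at 1.16 and part of the gate, were left out of this test. The pan-macrophage list also holds markers that neutrophils carry, such as Itgam, so its median alone cannot test dilution by neutrophils. Of its members, Csf1r, Adgre1, Mertk and Cd68 were at −0.03, 0.04, −0.09 and 0.00, and Fcgr1 was at −0.30. Sequencing depth is argued against by the WTKL libraries, whose totals differ 1.48-fold and whose list means differ by 0.03, a share of 0.051 of the group difference of −0.61. Fewer T and NK cells carried through the sort, which took CD11b and CD64 positive cells, stay open. The interferon-gamma list kept a median of 61.7% of its WTKL level (quartiles 56.1% and 68.2%) and the T and NK list 62.5% (59.5% and 70.5%). With shares so close, such cells could account for the whole fall only if nearly all of the list's RNA came from them. The lists lost 678 and 53.1 FPKM in sum, and how much interferon-response RNA such cells hold was not measured. The genotype of the marrow stays open too as a biological explanation and was not tested apart from these markers, which go with it in these libraries.

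Siglecf rose in cells sorted as low for its protein. If more alveolar macrophages had entered the gate, their other markers should have risen too. How far each should rise depends on its level in those cells, which was not measured. The third quartile of 18 other markers was 0.24 (median 0.07), below the Siglecf change of 1.16 (95% interval 0.96 to 1.36). Several were far more abundant in WTKL than Siglecf at 6.42 FPKM, such as Atp6v0d2 at 265.0 and Itgax at 125.4. A small carried share would barely move those, so this test cannot exclude one. Of less abundant markers, Fabp4, at 7.48 FPKM in WTKL, rose by 0.27 and Marco, at 23.8, by 0.61. In this list 9 of the 19 genes stand in another list too. Its mean log2 value was 5.03 and 5.31 in WTKL replicates 1 and 2, against 5.28 and 5.37 in LYZKL. Neutrophils, which tumors can induce to express Siglecf, would be gated out by Ly6G, yet 9 of their 15 markers rose when adjusted over the list alone (0 over all genes), with a list median of 0.89, an adjusted p of 0.41 with an estimated correlation, and S100a9 at 3970 FPKM in LYZKL. The excess over WTKL of the 9 raised neutrophil markers was 1.48 to 2.93 times as large in LYZKL replicate 1 as in replicate 2 (median 1.6), while that of Siglecf was 0.99 times as large, which 2 libraries leave undecided. Neutrophil RNA, a small share of alveolar macrophage RNA and a change in the sorted macrophages cannot be told apart as the source of Siglecf here, and each may contribute.

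Tmem173 and Cd38 share a numerical oddity. A transcript length outside the annotation is argued against, since 0 read numbers up to 40000 gave whole reads in all 4 libraries for either gene at any length. Of the 19226 rows above 0 in every library, 19224 gave whole reads, and these 2 did not. The 13 tested rows with a 0 in some library were not searched over lengths and do not bear on this. A rare failure of the search was not excluded. At their annotated lengths of 2741 and 3890 bases, 0 of the 8 values were whole reads within 0.003 and 1 within 0.05, the tolerance used for other rows at the annotated length, where 0.8 are expected by chance, with Tmem173 at 226.529, 238.4855, 651.3149 and 955.7085 reads and Cd38 at 227.9958, 218.4536, 619.3264 and 985.8676 (LYZKL replicates 1 and 2, then WTKL replicates 1 and 2). That these rows were made in another way than the rest may explain this and cannot be told apart from other causes with 1 table. Reads counted in simple fractions would have given whole numbers at a multiple of the length, which the search did not find. Other fractional counting or any later step stays open, and no biological explanation was tested.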
